A study of Mus musculus with 21 samples.

How the data were processed

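The study measured RNA from mouse splenic T cells that had been activated with CD3/CD28 beads and cultured for 48 h in fresh medium, in WEHI-3B (AML) conditioned medium or in conditioned medium of dendritic cells derived from bone marrow. The conditioned media were filtered supernatants of cultures, and CD8+ cells were isolated again by magnetic separation before RNA extraction, per the labels' protocols. The 21 samples fall into 3 groups of 7 biological replicates by the labels. The labels number the replicates from 1 to 7 in each group and do not say whether a number stands for the same mouse or day. One label field names a reticular cell type in place of T cells; all other fields name CD8+ T cells, and the groups follow those. Labelled cDNA was made with the Affymetrix WT Pico kit and hybridised to 1-colour arrays.

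The deposited values are log2 expression values per transcript cluster, made by the authors with RMA in the R package oligo, per the submitters' processing notes, which give no versions. RMA corrects background, normalizes by quantiles and summarises the probes of a transcript cluster. It gives no separate signal over background, so the detection of a gene on 1 array was not assessed, and low values lie near a floor where differences are compressed. The table had 22203 transcript clusters, of which 19572 had 1 gene symbol in the platform's annotation, 0 had several and 2631 had none. Symbols were checked against a mouse gene table of assembly GRCm38.p6 through the gene identifiers, which changed 0 of them. For the 55 symbols with more than 1 transcript cluster the one with the highest mean over all arrays was kept, which left 19505 genes. No filter on level was applied.

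Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 21 arrays in 1 fit, without covariates. The 3 groups thus shared 1 estimate of the spread per gene. Where the AML arrays spread far more than the others, standard errors are understated in the AML comparisons and overstated for DC-conditioned against fresh medium. The 3 comparisons were AML-conditioned against fresh medium, DC-conditioned against fresh medium, and AML-conditioned against DC-conditioned medium. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Log2 differences are given with their standard errors, levels as mean and SD, and all tests were two-sided. The number of arrays limits the precision.

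Gene lists were fixed before the data were examined: 38 of pathways, 15 of cell types and 2 of control genes. The 52 lists with at least 5 measured members entered the tests of all 3 comparisons, and those of erythroid cells, gamma delta T cells and sex-linked genes did not. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, which tests whether the members move in 1 direction without comparing them with other genes. List p-values were adjusted over the lists of a comparison. The list mean of an array is the mean log2 value of the members minus its average in fresh medium.

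The genes named in the text come from a set drawn by a rule that was fixed beforehand, and not every gene of the set is printed in every comparison. Apart from 17 genes fixed by name, the rule picks genes by their results in these data. Their differences and p-values are therefore those of selected genes. In each comparison the set held the 8 called genes with the largest rise and the 8 with the largest fall, without clone names, small RNAs and antigen receptor segments. From each called list came the 2 called members with the smallest adjusted p in the direction of the list. Added to these were 17 genes followed in every comparison whatever their result, of which 16 were measured under their names. *Tcf7*, the remaining one, is not analysed here. A few further genes are named outside the rule, to describe a list or a set of arrays, and were also chosen after their values were seen: *Pgd*, *Itgae* after DC-conditioned medium, and in the closing section *Nt5e*, *Dapk2* and the genes that differ between sets of replicates.

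Comparisons that share arrays were set against 100 random reassignments of the residual arrays to 3 groups, against 100 that kept 3 of replicates 1 to 3 in each group (chosen after the data were seen), and against divided arrays. Each group comparison was repeated on 100 splits of its 14 arrays, the real one included, and the list counts also on 100 splits with replicates 1 to 3 and 4 to 7 in equal shares on both sides, which was chosen after the data were seen. Chosen before the data were examined were these alternatives: the replicate number as a block or as a random effect, a further quantile normalization, centring of each array on its median, a filter at the 25th percentile of mean level, the mean of all transcript clusters of a symbol, eBayes with trend and robust estimation, array weights, a fit of the compared groups alone, Welch tests per gene, transcript clusters without a symbol included, leaving out each array in turn, and both other list tests. Chosen after the data were seen were the fits without AML replicates 4 and 5, with a block for replicates 1 to 3 and 4 to 7, and within each of those sets.

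The fit was tested on simulated values for AML-conditioned against fresh medium, with the real residual spread of 19505 genes and 200 changed genes. Of those changed by log2 1, 100% were recovered, and of those changed by log2 0.5, 81%. Among the unchanged genes 11 were called, and a group without change gave 0 calls. The simulated noise was independent between genes, had the same spread in all groups and held no sets of replicates, unlike the arrays. These values therefore test the code and do not give the yield or the false calls on the arrays.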

Results

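Gene expression was measured on 21 Affymetrix arrays in mouse CD8+ T cells that had been cultured for 48 h in 1 of 3 media. T cells from the spleens of wildtype mice were activated through CD3 and CD28 with beads. They were then kept in fresh medium, in medium conditioned by WEHI-3B cells, or in medium conditioned by dendritic cells grown from bone marrow (DC). WEHI-3B is a mouse myelomonocytic leukaemia line that serves here as a model of acute myeloid leukaemia (AML). Each medium had 7 biological replicates, and CD8+ cells were isolated again with magnetic beads before RNA extraction. The precision of each value was limited by the 7 arrays per group, with a median standard error of 0.0937 on the log2 scale for a difference between media.

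The marker genes *Cd3e*, *Cd8a* and *Cd8b1* differed little between the 3 groups. In the fresh-medium arrays *Cd3e*, a subunit of the T cell receptor complex, had a log2 level of 11.76 ± 0.13 (SD, n = 7), *Cd8a* 11.69 ± 0.04 and *Cd8b1* 11.70 ± 0.09. None of these genes passed the test in any comparison, and the largest difference among them was 0.15 (SE 0.08), for *Cd3e* between AML-conditioned and fresh medium. One label field names CXCL12-abundant reticular cells against all other labels. *Cxcl12* had a log2 level of 5.45 ± 0.19 in fresh medium and differed from it by 0.05 (SE 0.08) after AML-conditioned and by -0.10 (SE 0.08) after DC-conditioned medium.

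The comparison of AML-conditioned with fresh medium asked which transcripts of CD8+ T cells respond to soluble products of leukaemia cells. Members of a fixed list of TGF-beta response genes rose. Genes of glycolysis and the hypoxia response were lower in 5 of 7 AML arrays than in all 14 other arrays, and these lists passed with a preset correlation between genes and not with an estimated one. The strongest rises were *Ccr8*, a chemokine receptor, 4.46-fold (log2 2.16, SE 0.33, adjusted p = 0.00104), and *Cish*, a feedback inhibitor of cytokine signalling, 3.37-fold (log2 1.75, SE 0.31, adjusted p = 0.00324). In AML replicates 6 and 7 *Ccr8* was at 5.51 and 6.30, against 5.25 and 6.25 in fresh replicates 6 and 7. *Cish* was at 7.27 and 7.70 there, against 7.05 and 7.67. Each of the 2 genes lost its call under 1 of 34 alternatives. *Itgae*, which encodes the integrin CD103, rose 3.07-fold from 6.44 ± 0.34 to 8.06 ± 0.26 (SD, n = 7) and lay above every fresh-medium array in 7 of 7. *Gzma*, which encodes the serine protease granzyme A, fell by 2.23 on the log2 scale (SE 0.40, adjusted p = 0.00324) to a level of 6.77 ± 1.23, below every fresh-medium array in 7 of 7. *Itga7*, an integrin chain, fell by 1.81 (SE 0.19, adjusted p = 3.14e-06). Across the 19505 genes tested with limma, 541 passed an adjusted p of 0.05, 253 of them higher and 288 lower, and 41 of these changed at least 2-fold. Of 52 gene lists tested, 10 were called up and 6 down with a preset correlation, and 1 passed with an estimated one. AML replicates 4 and 5 stood apart from the other 19 arrays on the second component of the residuals, at -0.55 and -0.53 against -0.30 to 0.32. Without both of them 111 genes passed, 7 of them at least 2-fold, and without 1 array the count fell to 249 (AML replicate 4), 218 (AML replicate 5), 299 (fresh replicate 2) or 341 (fresh replicate 4), and the 2-fold count moved to 24, 25, 67 or 68 without AML replicate 4, 5, 6 or 7. With the replicate number as a block 1012 genes passed, 521 higher and 491 lower, with a block for replicates 1 to 3 and 4 to 7 1026, with the 2 groups alone 246 and with an unmoderated test per gene 21. Centring each array on its median gave 289 higher and 197 lower calls.

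**Figure D1:**
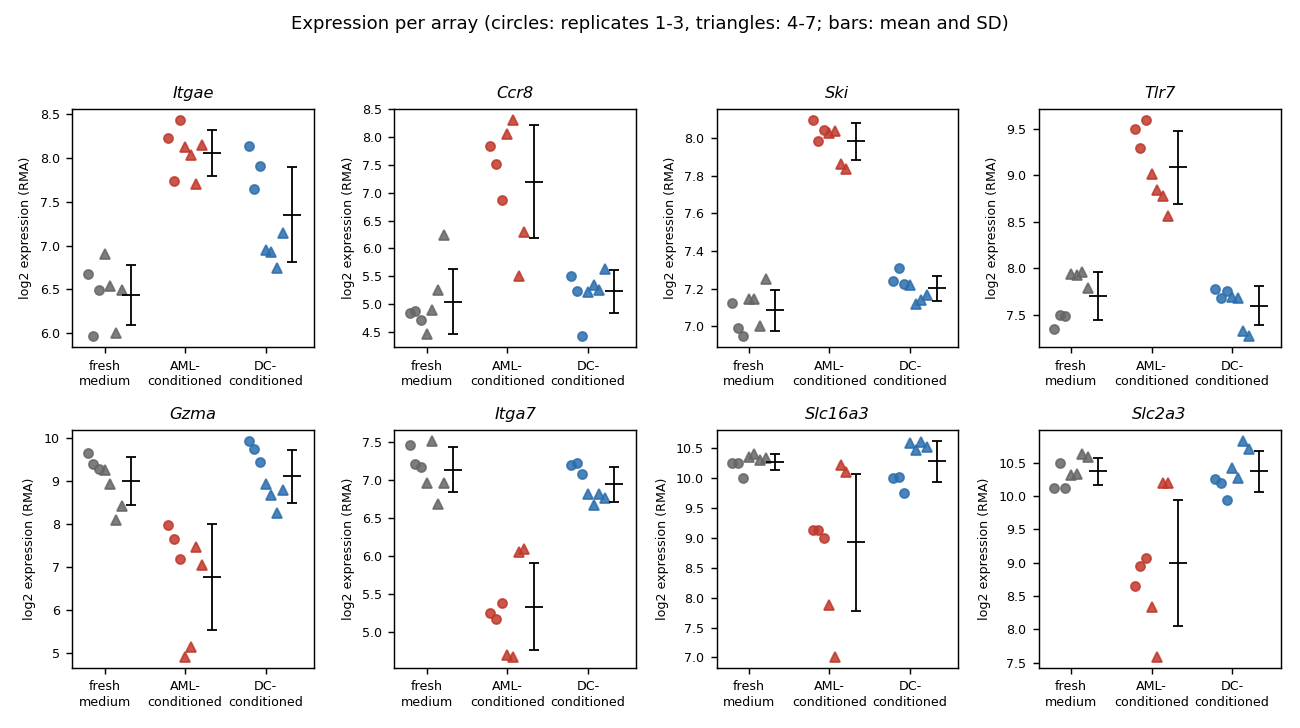
Log2 expression (RMA) of 8 genes in each of the 21 arrays, by medium. Circles are replicates 1 to 3, triangles are replicates 4 to 7, and bars give the mean and SD of 7 arrays. *Itgae*, *Ski* and *Tlr7* were above all fresh-medium arrays in 7 of 7 AML arrays, and *Gzma* and *Itga7* were below them in 7 of 7.

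Genes of the TGF-beta response list rose together after AML-conditioned medium. Of 15 measured members, 10 rose, none fell and 5 did not pass, and 12 rose when adjusted over the list alone. *Ski*, a transcriptional corepressor of SMAD proteins, rose by 0.90 on the log2 scale (SE 0.06, adjusted p = 4.31e-09), *Pmepa1*, an inhibitor of TGF-beta signalling, rose by 0.82 (SE 0.08, adjusted p = 1.94e-06), and *Gpr83*, a receptor expressed in regulatory T cells, rose by 1.42 (SE 0.35, adjusted p = 0.0293). The list's median was 0.79, and it passed with the preset correlation (adjusted p = 2.14e-21) and with an estimated one (adjusted p = 0.00209). All 7 AML arrays, with list means between 0.38 and 1.23 relative to the fresh-medium mean, lay above all 14 other arrays. The difference in list means was 0.83 in replicates 1 to 3 and 0.78 in replicates 4 to 7. The members *Ccr8*, *Cish* and *Itgae* also belong to 1 or more of the other lists; the other 12 members had 7 rises and a median of 0.60. *Cd4*, the coreceptor of helper T cells, was higher in the same arrays by 0.79 (SE 0.18, adjusted p = 0.0150), while the CD4 T cell list did not pass (median 0.14, adjusted p = 0.0649). The calls of *Gpr83* (adjusted p = 0.0532) and *Cd4* (adjusted p = 0.0622) ended without AML replicates 4 and 5, at log2 differences of 0.72 and 0.81. The call of *Gpr83* also ended without fresh replicate 2 or 3 or AML replicate 4 or 5 alone, at differences of 1.07 to 1.38 (adjusted p = 0.0533 to 0.0771). A second list of 12 other TGF-beta targets, weighed in the closing section, had a median of -0.03, with 1 rise and 1 fall.

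Glycolysis and hypoxia genes were lower in most arrays after AML-conditioned medium. In the hypoxia response list 13 of 19 members fell and none rose (16 falls when adjusted over the list alone), with a median of -0.77. In the glycolysis list 10 of 16 fell and none rose (15 adjusted over the list alone), with a median of -0.48. The glucose transporter genes *Slc2a3* and *Slc2a1* fell by 1.38 (SE 0.27, adjusted p = 0.00724) and by 0.92 (SE 0.21, adjusted p = 0.0169). *Egln3*, an oxygen sensor that hypoxia induces, fell by 1.46 (SE 0.35, adjusted p = 0.0234), *Ak4*, a mitochondrial adenylate kinase, fell by 1.53 (SE 0.33, adjusted p = 0.0138), and *Aldoa*, an aldolase of glycolysis, fell by 0.47 (SE 0.10, adjusted p = 0.0111). The hypoxia and glycolysis lists passed with the preset correlation (adjusted p = 1.19e-16 and 1.60e-15) and not with an estimated one (adjusted p = 0.288 and 0.291). The arrays differed in degree. In 5 of 7 AML arrays the hypoxia and glycolysis means lay below all 14 other arrays, and in AML replicates 6 and 7 they overlapped them. The hypoxia list mean was -0.08 and -0.14 in AML replicates 6 and 7 and -1.21 and -1.46 in AML replicates 4 and 5. By replicate number, the hypoxia means differed by -0.69 in replicates 1 to 3 and by -0.78 in replicates 4 to 7, and the glycolysis means by -0.56 and -0.60. Over the alternatives the hypoxia median ran from -0.87 to -0.51 and the glycolysis median from -0.56 to -0.30. Without AML replicates 4 and 5 the calls of *Slc2a1* (log2 -0.59, adjusted p = 0.110), *Egln3* (log2 -0.83, adjusted p = 0.0937) and *Ak4* (log2 -1.07, adjusted p = 0.112) ended. *Aldoa* differed by -0.52 to -0.29 over 34 alternatives and lost its call in 2 of them. Without AML replicate 4 alone *Slc2a1* (log2 -0.81, adjusted p = 0.0502) and *Egln3* (log2 -1.24, adjusted p = 0.0637) did not pass, nor did *Egln3* without fresh replicate 2 (log2 -1.43, adjusted p = 0.0501).

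**Figure D2:**
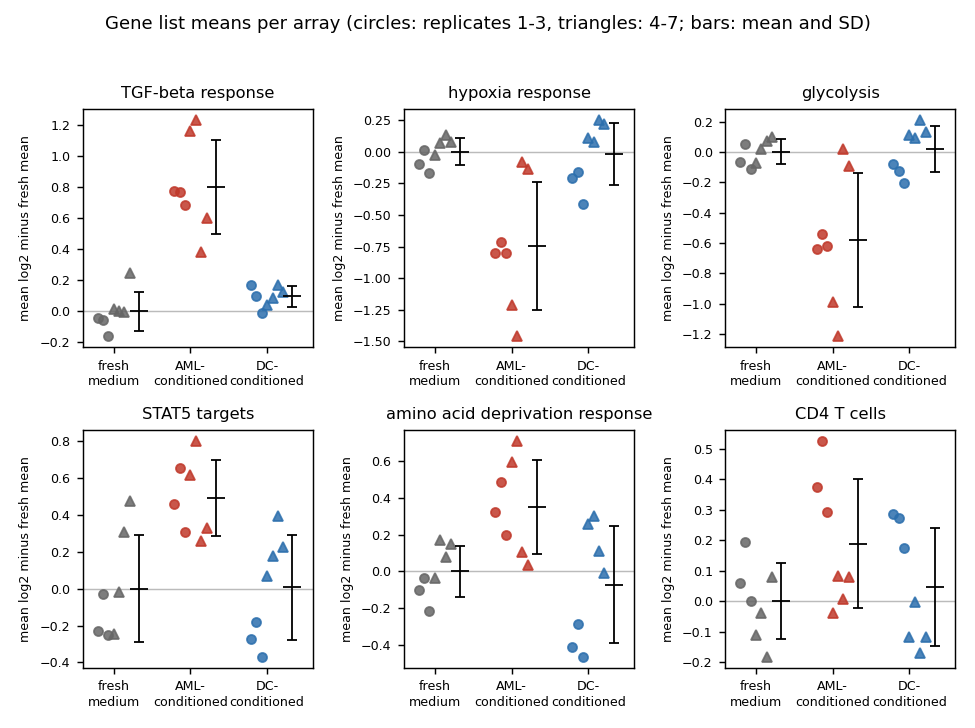
Mean log2 value of the members of 6 gene lists in each array, minus the mean of the 7 fresh-medium arrays. Circles are replicates 1 to 3, triangles are replicates 4 to 7, and bars give the mean and SD of 7 arrays. The TGF-beta list was between 0.38 and 1.23 in the AML arrays, above all others, and the hypoxia list ran from -1.46 to -0.08 in them.

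Lactate export was represented by *Slc16a3*, which encodes the monocarboxylate transporter MCT4 and fell by 1.35 (SE 0.32, adjusted p = 0.0240), from 10.27 ± 0.13 to 8.92 ± 1.15. Its chaperone gene *Bsg* fell by 0.49 (SE 0.10, adjusted p = 0.0103), and *Pdk1*, a kinase that inhibits pyruvate dehydrogenase, fell by 0.51 (SE 0.09, adjusted p = 0.00481). Of the 16 members of the lactate and pyruvate list, 3 fell, none rose and 13 did not pass (5 falls adjusted over the list alone; adjusted p = 0.00141, and 0.365 with an estimated correlation). *Slc16a1*, which encodes MCT1, differed by -0.03 (SE 0.12), *Ldha*, the muscle-type lactate dehydrogenase subunit, by -0.18 (SE 0.07, adjusted p = 0.220) and hexokinase *Hk2* by -0.69 (SE 0.20, adjusted p = 0.0655), and none of them passed. Fatty acid oxidation (16 members, 0 called) had a median of -0.17 and an adjusted p of 0.000205 (0.323 with an estimated correlation), and mitochondrial respiration (26 members, 0 called) a median of -0.07 and an adjusted p of 0.0195 (0.730 with an estimated correlation). When AML replicates 4 and 5 were left out, *Slc16a3* differed by -0.76 (adjusted p = 0.0756) and *Bsg* by -0.34 (adjusted p = 0.0782), and neither passed, and the fatty acid oxidation median was -0.08 (adjusted p = 0.0479). The fatty acid oxidation means differed by -0.06 in replicates 1 to 3 and by -0.21 in replicates 4 to 7. *Slc16a3* did not pass without AML replicate 4 alone (log2 -1.18, adjusted p = 0.0669), respiration did not without fresh replicate 5 or 7 or AML replicate 3 (adjusted p = 0.0525 to 0.0870), and *Hk2* passed without DC replicate 3 or AML replicate 6 or 7 (log2 -0.85 to -0.69) and with the replicate number as a block (log2 -0.69, adjusted p = 0.00543).

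Some cytokine genes and some targets of cytokine signalling rose after AML-conditioned medium, in lists that did not pass with an estimated correlation. In the STAT5 target list 5 of 18 members rose and none fell (11 rises adjusted over the list alone; median 0.46, adjusted p = 4.25e-09, and 0.291 with an estimated correlation). *Osm*, which encodes the cytokine oncostatin M, rose by 0.99 (SE 0.21, adjusted p = 0.0126). Of 22 effector cytokines and chemokines, 4 rose, 1 fell and 17 did not pass (adjusted p = 0.000563, and 0.323 with an estimated correlation). Among them *Lta* and *Tnf*, which encode lymphotoxin alpha and tumour necrosis factor, both rose by 1.24 (SE 0.27 and 0.26, adjusted p = 0.0146 and 0.0117), while *Ifng* differed by 0.45 (SE 0.27, adjusted p = 0.443). The IL-4 and STAT6 target list had 4 rises among 16 members (adjusted p = 0.00148, and 0.291 with an estimated correlation), with *Il24*, a cytokine of the IL-10 family, up by 1.59 (SE 0.31, adjusted p = 0.00614). The NF-kB target list had 4 rises among 18 members (adjusted p = 0.000117, and 0.445 with an estimated correlation). *Lif*, another cytokine gene, rose by 1.34 (SE 0.30, adjusted p = 0.0158), and *Tlr7*, a receptor for single-stranded RNA, rose by 1.38 (SE 0.14, adjusted p = 3.14e-06) and lay above every fresh-medium array in 7 of 7. Without AML replicates 4 and 5 the calls of *Osm* (log2 0.97), *Lta* (0.83), *Tnf* (0.96), *Il24* (1.19) and *Lif* (1.08) ended (adjusted p = 0.0554 to 0.135), as did that of the NF-kB list (median 0.02, adjusted p = 0.0616), and *Tlr7* passed at 1.44. Without AML replicate 5 alone the NF-kB median was 0.13. In AML replicates 6 and 7 *Osm*, *Lta*, *Tnf*, *Il24* and *Lif* lay within the range of the fresh-medium arrays. There *Tnf* was at 7.63 and 8.165, against 7.773 and 8.393 in fresh replicates 6 and 7. The STAT5 list means were 0.26 and 0.33 there, against 0.30 and 0.47 in those fresh arrays. In replicates 1 to 3 and 4 to 7 alone *Osm* differed by 1.64 and 0.50 (adjusted p = 0.000623 and 0.349) and *Tlr7* by 2.02 and 0.90, and the medians were 0.53 and 0.29 for STAT5 targets, 0.02 and 0.20 for effector cytokines and 0.06 and 0.27 for NF-kB targets.

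Some amino acid and activation genes also rose, in lists that did not pass with an estimated correlation. The amino acid deprivation list had 4 rises and 2 falls among 25 members (17 and 2 adjusted over the list alone; median 0.38, adjusted p = 3.04e-08, and 0.323 with an estimated correlation). *Chac1*, a glutathione-degrading enzyme, rose by 1.05 (SE 0.22, adjusted p = 0.0119) and *Slc7a3*, a cationic amino acid transporter, by 1.18 (SE 0.28, adjusted p = 0.0221). The amino acid transport list had 3 rises and 1 fall among 15 members (adjusted p = 1.52e-05, and 0.291 with an estimated correlation), among them the glutamine transporter *Slc1a5* at 0.50 (SE 0.10, adjusted p = 0.0107). Of 23 activation and costimulation receptors 3 rose and none fell (adjusted p = 0.00141, and 0.323 with an estimated correlation), with *Egr1*, an immediate-early transcription factor, up by 1.24 (SE 0.32, adjusted p = 0.0350). None of these 4 genes passed without AML replicates 4 and 5, at 0.74 for *Chac1*, 0.90 for *Slc7a3*, 0.35 for *Slc1a5* and 0.78 for *Egr1*. *Slc7a3* also did not pass without AML replicate 4 or 5 alone (1.05 to 1.07, adjusted p = 0.0618 and 0.0665), nor *Egr1* without fresh replicate 1, 3, 4 or 5 or AML replicate 4 or 5 (1.05 to 1.27, adjusted p = 0.0523 to 0.101). In replicates 1 to 3 and 4 to 7 alone *Egr1* differed by 0.71 and 1.65, and the activation receptor medians were 0.40 and 0.12. In AML replicates 6 and 7 the deprivation means were 0.11 and 0.04, against 0.08 and 0.15 in fresh replicates 6 and 7. Activation receptor means were 0.08 and 0.11, against 0.17 and 0.30. *Egr1* was at 8.30 and 8.55 there, against 8.40 and 8.61, and *Chac1* at 5.76 and 5.49, against 5.62 and 5.77. *Slc7a3* (8.04 and 7.86, against 7.71 and 7.62) and *Slc1a5* (10.16 and 10.42, against 10.06 and 10.185) were higher there. Transport means were 0.14 and 0.10, against 0.05 and 0.11.

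After AML-conditioned medium the list of MYC targets and ribosome biogenesis had 0 called of 23 members, a median of 0.26 and an adjusted p of 0.000216 (0.730 with an estimated correlation), and *Myc* itself differed by 0.40 (SE 0.11, adjusted p = 0.0573). Interferon gamma induced genes (2 rises of 20, median 0.07) and mitosis genes (1 fall of 27, *Cenpa*, median -0.15) passed with adjusted p of 0.00731 and 0.000429 (0.445 and 0.730 with an estimated correlation). Mitosis means differed by 0.08 in replicates 1 to 3 and by -0.32 in replicates 4 to 7. Granzyme B and perforin genes did not pass, with *Gzmb* at -0.16 (SE 0.15) and *Prf1* at -0.02 (SE 0.13), nor did the genes of the inhibitory receptor PD-1, *Pdcd1*, at 0.06 (SE 0.11) and of the IL-2 receptor alpha chain, *Il2ra*, at 0.53 (SE 0.16, adjusted p = 0.0725). Without AML replicates 4 and 5 the MYC (median 0.04, adjusted p = 0.222) and interferon gamma lists (0.04, adjusted p = 0.0838) did not pass and the mitosis median turned to 0.03; without AML replicate 4 alone the mitosis median was -0.07 (adjusted p = 0.0655) and the interferon gamma median 0.04, and without AML replicate 5 alone mitosis was at -0.08 and MYC targets at 0.15. *Cenpa* did not pass without any 1 of fresh replicates 1 to 5, DC replicates 2, 4, 5 and 7 and AML replicates 2, 4 and 5 (adjusted p = 0.0505 to 0.113), *Myc* passed without fresh replicate 6 or 7 or AML replicate 6 (0.43 to 0.47), and *Il2ra* without DC replicate 3 or fresh replicate 6 or 7 (0.53 to 0.61). With the replicate number as a block both passed (adjusted p = 0.0424 and 0.0333).

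The comparison of DC-conditioned with fresh medium tested medium conditioned by cells that are not leukaemic. No gene passed in this comparison. With limma 0 genes had an adjusted p under 0.05, 1251 had an unadjusted p under 0.05, and an unmoderated test per gene with the same adjustment also gave 0. A block for the replicate number or for both sets of replicates gave 1 gene each, array weights 2, and leaving out 1 array 0 to 2. *Slc16a3* differed by 0.01 (95% interval -0.66 to 0.68), *Slc2a1* by -0.05 (-0.48 to 0.38), *Gzmb* by 0.06 (-0.26 to 0.37) and *Ifng* by -0.46 (-1.02 to 0.09). These intervals use 1 spread per gene shared by all 3 groups. *Slc16a3* ran from 7.01 to 10.22 in AML, 10.01 to 10.41 in fresh and 9.76 to 10.61 in DC arrays. Its interval is therefore widened by the AML arrays. *Itgae* differed by 0.91 (SE 0.19, adjusted p = 0.302), with 6 of 7 DC arrays above every fresh-medium array and levels between 7.64 and 8.14 in DC replicates 1 to 3. *Cd4* differed by 0.25 (SE 0.18), and *Hk2*, *Ldha*, *Myc*, *Prf1*, *Pdcd1*, *Il2ra* and *Slc16a1* differed by between -0.04 (*Pdcd1*) and 0.08 (*Hk2*). Of 52 lists, 6 passed with the preset correlation, without a called member in any of them. The unfolded protein response was highest, with a median of 0.13 (adjusted p = 0.00843), and cholesterol synthesis, pentose phosphate and nucleotide synthesis, MYC targets and respiration had medians between 0.04 and 0.08. Targets of cyclic AMP and prostaglandin E2 had a median of -0.15 (adjusted p = 0.0259). None of the 6 passed with an estimated correlation (adjusted p = 0.938 for each). In replicates 1 to 3 alone the medians of pentose phosphate and nucleotide synthesis, respiration and MYC targets were -0.06, -0.05 and -0.10. Without DC replicate 4 or DC replicate 5 or fresh replicate 3, all 6 lists lost the call (MYC targets at a median of 0.05, 0.03 and 0.04), and the calls of 1 to 5 of them also ended without DC replicate 6 or 7 or fresh replicate 1, 2, 4, 6 or 7 (MYC targets at 0.03 without DC replicate 6).

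The comparison of AML-conditioned with DC-conditioned medium set medium from leukaemia cells against medium used by another cell type, and how far the cells had used up either medium was not measured here. The TGF-beta response list was higher, and the hypoxia and glycolysis lists were lower with a preset correlation and did not pass with an estimated one. *Gzma* was lower by log2 -2.34 (SE 0.40, adjusted p = 0.00270). *Mt2* and *Mt1*, which encode metal-binding proteins, were lower by -2.07 (SE 0.50, adjusted p = 0.0239) and -1.76 (SE 0.43, adjusted p = 0.0269). *Prdm1*, which encodes the effector transcription factor BLIMP-1, was lower by -1.46 (SE 0.32, adjusted p = 0.0153). *Ccr8* was higher by 1.97 (SE 0.33), *Egr1* by 1.82 (SE 0.32), *Tlr7* by 1.49 (SE 0.14), *Pmepa1* by 0.95 (SE 0.08) and *Ski* by 0.78 (SE 0.06). Over the alternatives the difference of *Egr1* ran from 1.17 to 2.30. Of 52 lists 12 were called up and 11 down with the preset correlation, and 1 passed with an estimated one. In total 466 genes passed, 220 higher and 246 lower, and 48 of them changed at least 2-fold. Of these calls 130 higher and 152 lower ones were shared with the comparison against fresh medium and 0 went the opposite way, where independent lists would share 2.85 and 3.63. Unchanged groups in the place of the AML arrays gave 0.05 shared calls on average. Such groups have hardly any calls to share, so this value does not show what the common AML arrays add. With the AML arrays divided between both comparisons the mean was 14.7 shared calls, where each comparison had fewer AML arrays to call genes with. Without AML replicates 4 and 5, 92 genes passed, 6 of them at least 2-fold. Leaving out 1 array gave 220 (AML replicate 4), 242 (AML replicate 5), 308 (DC replicate 4), 289 (DC replicate 7) or 784 (AML replicate 6), with 24 and 29 at 2-fold without AML replicate 4 or 5. With the replicate number as a block 784 genes passed, with a block for both sets of replicates 797, with the 2 groups alone 249 and with an unmoderated test per gene 7.

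The TGF-beta list had 9 rises and no fall among 15 members against DC-conditioned medium (median 0.68, adjusted p = 0.00336 with an estimated correlation), and its median was 0.32 in replicates 1 to 3 alone. Hypoxia genes (14 falls of 19, median -0.75) and glycolysis genes (12 falls of 16, median -0.50) passed with the preset correlation and had an adjusted p of 0.159 each with an estimated one. *Slc16a3* was lower by -1.36 (SE 0.32, adjusted p = 0.0234) and *Hk2* by -0.77 (SE 0.20, adjusted p = 0.0415). Of 28 interferon-stimulated genes 5 rose and none fell (adjusted p = 0.0499, and 0.465 with an estimated correlation), with *Ifit3*, an antiviral effector, up by 1.26 (SE 0.18, adjusted p = 0.000671) and above every DC array in 7 of 7. Of 17 naive and memory T cell genes 3 rose and none fell (adjusted p = 0.0211, and 0.465 with an estimated correlation), with *Il6ra*, the IL-6 receptor gene, at 0.89 (SE 0.16) and *Eomes*, a transcription factor of CD8+ T cells, at 0.79 (SE 0.14). Targets of cyclic AMP and prostaglandin E2 had 4 rises among 14 members (adjusted p = 0.000185, and 0.161 with an estimated correlation), among them the orphan nuclear receptor gene *Nr4a1* at 1.02 (SE 0.23). In the NRF2 oxidative stress list 4 of 17 members fell (adjusted p = 0.0494, and 0.430 with an estimated correlation), namely *Mt1*, *Mt2*, the heme oxygenase gene *Hmox1* and *Pgd*, an enzyme of the pentose phosphate pathway; the list's median was -0.08, and 0.04 in replicates 1 to 3 alone, where it did not pass. *Cd4* differed by 0.54 (SE 0.18, adjusted p = 0.110). Without AML replicates 4 and 5 the calls of *Mt2* (log2 -1.19, adjusted p = 0.126), *Prdm1* (log2 -0.91, adjusted p = 0.0831), *Hmox1* (log2 -0.66), *Slc16a3* (log2 -0.76, adjusted p = 0.0763) and *Hk2* (log2 -0.71, adjusted p = 0.219) ended, and *Mt1* and *Nr4a1* differed by -0.87 and 0.59. In replicates 1 to 3 alone the differences were -0.72 for *Prdm1*, -0.84 for *Slc16a3*, -1.11 for *Mt1*, -0.51 for *Hmox1*, 0.52 for *Il6ra* and 0.61 for *Nr4a1*. Leaving out 1 array ended the calls of *Mt1* (DC replicate 6 or 7 or AML replicate 4; adjusted p = 0.0569 to 0.0712), *Mt2* (the same or AML replicate 5; 0.0502 to 0.0689), *Slc16a3* (DC replicate 4, 6 or 7 or AML replicate 4; up to 0.0677) and *Hk2* (AML replicates 1 to 5, DC replicates 4 to 7, fresh replicates 2 and 6; 0.0506 to 0.0999), and *Cd4* passed without AML replicate 6 (0.67, adjusted p = 0.0181) and with the replicate number as a block (0.54, adjusted p = 0.0122). It also ended the calls of the naive and memory list (DC replicates 4 to 7, AML replicates 1 and 3; adjusted p up to 0.0938, median down to 0.03), the interferon-stimulated list (any array but DC replicates 1, 3, 4 and 5, fresh replicate 4 and AML replicates 4, 5 and 7; up to 0.186) and the NRF2 list (any but DC replicates 1 to 3, fresh replicate 4 and AML replicates 4 to 7; up to 0.127, median down to -0.03), and the cyclic AMP median was 0.17 without AML replicate 2.

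Effector and cell cycle lists were lower after AML-conditioned than after DC-conditioned medium with the preset correlation. Of 16 cytotoxic effector molecules 2 fell and none rose (median -0.18, adjusted p = 0.0125, and 0.353 with an estimated correlation), namely *Gzma* and the granzyme gene *Gzmm* at -0.40 (SE 0.11, adjusted p = 0.0453). Of 13 effector transcription factors 2 fell and none rose (median -0.20, adjusted p = 0.000450, and 0.161 with an estimated correlation), namely *Prdm1* and the nuclear receptor gene *Rora* at -0.73 (SE 0.15, adjusted p = 0.00849). S phase and mitosis genes, with 0 called of 27 in each, had medians of -0.14 and -0.17 (adjusted p = 0.000312 and 7.24e-07, and 0.490 and 0.454 with an estimated correlation). Also called were amino acid deprivation (9 rises and 1 fall of 25, median 0.45), amino acid transport (0.30), STAT5 targets (0.45), activation receptors (0.33), NF-kB targets (0.22), effector cytokines (0.16), IL-4 and STAT6 targets (0.14), interferon gamma induced genes (0.09), lactate and pyruvate (-0.12), respiration (-0.10), fatty acid oxidation (-0.13) and the unfolded protein response (-0.12), none of which passed with an estimated correlation. Over the alternatives the medians ran from 0.02 to 0.45 for NF-kB targets and from 0.03 to 0.26 for IL-4 and STAT6 targets. They ran from 0.21 to 0.71 for amino acid deprivation and from 0.21 to 0.58 for STAT5 targets. Lactate and pyruvate ran from -0.19 to -0.03 and respiration from -0.18 to -0.01. The cytotoxic (median -0.07), S phase (-0.06) and mitosis (-0.03) lists did not pass without AML replicates 4 and 5, nor did *Gzmm* (-0.38) and *Rora* (-0.58). In replicates 1 to 3 alone S phase and mitosis turned to 0.08 and 0.02, and the cytotoxic and effector transcription factor medians were -0.02 and -0.07. The call of *Gzmm* ended without 1 array for AML replicates 1, 2 and 4 to 7, DC replicates 1, 2, 3, 5 and 7 and fresh replicates 2, 3 and 5 (-0.42 to -0.33, adjusted p = 0.0506 to 0.121), and without AML replicate 4 the mitosis median was -0.09.

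Further genes of metabolism and effector function were compared between AML-conditioned and DC-conditioned medium. *Slc2a1* was lower by -0.87 (SE 0.21, adjusted p = 0.0236). *Ifng* differed by 0.91 (SE 0.27, adjusted p = 0.0730), *Il2ra* by 0.57 (SE 0.16, adjusted p = 0.0575), *Myc* by 0.36 (SE 0.11, adjusted p = 0.0954) and *Ldha* by -0.24 (SE 0.07, adjusted p = 0.0950), and none of these 4 passed. *Gzmb* differed by -0.22 (SE 0.15), *Prf1* by -0.04 (SE 0.13), *Pdcd1* by 0.10 (SE 0.11) and *Slc16a1* by -0.05 (SE 0.12). *Slc2a1* did not pass without AML replicates 4 and 5 (-0.54, adjusted p = 0.165) or without any 1 of DC replicates 4 to 7 and AML replicates 4 and 5 (-0.85 to -0.70, adjusted p = 0.0503 to 0.0689). In replicates 1 to 3 and 4 to 7 alone *Ifng* differed by 0.23 and 1.43 and did not pass. Calls were gained by *Ifng* without AML replicate 1 or 7 (1.02 to 1.11, adjusted p = 0.0238 to 0.0406), by *Ldha* without AML replicate 6 or 7 (-0.27) and by *Il2ra* without DC replicate 5 or 6, fresh replicate 1 or AML replicate 6 (0.57 to 0.64) and with the replicate number as a block (0.57, adjusted p = 0.0261).

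The effects of both conditioned media against fresh medium were set side by side across genes, which are not independent replicates. The log2 differences correlated at r = 0.350 over 19505 genes, and unchanged groups set against the same fresh-medium arrays gave 0.488 ± 0.158 (SD over 100 simulations), or 0.4995 ± 0.140 with 3 of replicates 1 to 3 kept in each group. The covariance was 0.00673 against a simulated 0.00515, or 0.00460 with the sets kept. With the fresh-medium arrays divided between the comparisons the correlation averaged 0.0279, between -0.133 and 0.158. In the main fit no gene was called in both comparisons. Leaving out 1 array gave 0 to 1 such genes, and the fits with a block or with array weights also gave shared calls.

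**Figure D3:**
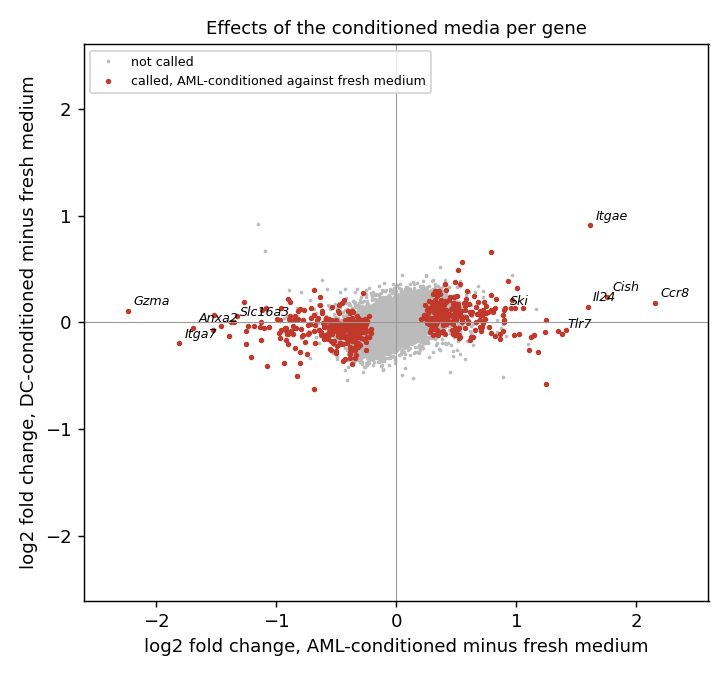
Log2 difference from fresh medium per gene, for AML-conditioned medium on the horizontal axis and DC-conditioned medium on the vertical axis. The 541 genes called after AML-conditioned medium are red and all others are grey. Differences ran from -2.23 for *Gzma* to 2.16 for *Ccr8* along the horizontal axis, and no gene was called along the vertical axis.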

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

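The tests for carry-over of CD4 T cells, for AML replicates 4 and 5, for a shared batch behind the hypoxia genes and for replicate numbers as batches were chosen only after the results they concern had been seen. The other tests in this part were fixed before their results were known, except for 1 change in how a verdict was reached that is given with its test, and the bound for the shared batch was also redrawn after its result. The immediate-early list was fixed before its own test, but after a gene of this kind had been seen to differ in these arrays.

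Among 276 groups of 7 arrays, for 66 named genes and 26 called lists, 11 held 1 array far from the other 6 by Dixon's criterion, about the rate that chance gives (1 in 20 groups), and 5.63% of the groups of all genes passed it as well. Fresh replicate 3 was low in *Slc16a3* (10.01, others 10.26 to 10.41), *Slc2a1* (10.95, others 11.16 to 11.31) and *Pfkp* (11.08, others 11.19 to 11.23). Fresh replicate 7 was high in *Il24* (5.01, others 3.57 to 4.04) and in the TGF-beta list mean (0.247, others -0.16 to 0.02). *Pdcd1* was low in fresh replicate 1 (5.56, others 5.82 to 5.92) and in DC replicate 7 (5.23, others 5.78 to 6.05). *Anxa2* was high in fresh replicate 2 (9.76, others 9.41 to 9.56), *Ccr8* low in DC replicate 3 (4.43, others 5.22 to 5.62), *Il2ra* high in AML replicate 2 (9.52, others 8.83 to 9.10) and *Mgarp* high in DC replicate 6 (7.06, others 6.62 to 6.81).

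The first pattern weighed is the rise of the TGF-beta list after AML-conditioned medium. Carry-over of CD4 T cells is not decided by the fit with the CD4 list mean of each array as a covariate, where the median was 0.790 as without it. That list mean did not always follow *Cd4*: in AML replicate 4 it was -0.04, while *Cd4* was at 8.38, above every fresh-medium array. A pair of AML arrays as the whole cause of the rise is opposed by the fit without AML replicates 4 and 5, where the median was 0.716 (0.629 against DC-conditioned medium). TGF-beta activity in the AML-conditioned medium is a candidate explanation that was not borne out by a second list of 12 other targets: its median was -0.03 (camera p with an estimated correlation = 0.681), with *Nt5e* higher, *Dapk2* lower and 5 of 12 above 0. The prediction written beforehand counted a median under 0.05 against this explanation; the demand that it lie below that bound by more than its bootstrap error of 0.0883 was added after the result was seen and leaves the explanation open. TGF-beta was not measured in the media here, and serum, cytokines or used nutrients could raise some of these genes too, which was not tested.

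The second pattern is the unequal fall of hypoxia and glycolysis genes between AML arrays. Differences in signal of whole arrays were weighed with random lists of the same size and level: the share with as large an SD over the AML arrays was 0.0001, the smallest that 10000 lists can give. Genes at large thus did not share the spread. The values had been normalized by quantiles, which leaves random lists little room to spread (median SD 0.043). The quality of an array is therefore not tested by this. A batch of T cells that moves all conditions alike is opposed as the whole cause: subtraction of the fresh and DC arrays of the same number left 0.947 of the SD of the AML arrays (jackknife error 0.165), and whatever the numbering the SD was 0.506 in AML, 0.105 in fresh and 0.247 in DC arrays. One response of differing strength may account for part of it: scaling each array by the strength measured on genes outside both lists brought the SD to 0.471 of its value, just under the bound of 0.5 set beforehand but within its jackknife error of 0.283 (0.371 to 0.687 without 1 array). Whether it followed the batch of conditioned medium, the density of the cells or T cells that differ only in this medium is not in the labels and was not tested.

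The third pattern is a difference between replicates 1 to 3 and 4 to 7 in all 3 media: 405 genes were apart in fresh, 227 in AML and 1795 in DC arrays, and 2839 over all arrays. The numbers may mark shared batches: of the 35 splits of the numbers into 3 and 4, this 1 gave the highest correlation of residuals between media, 0.129 against 0.102 for the next, although the split had been noticed in the same data. Such splits cannot find a further division. On the third component of the residuals replicates 4 and 5 lay below 6 and 7 in each medium. The values were -0.33 and -0.36 against 0.14 and 0.165 in fresh arrays. They were -0.09 and -0.29 against 0.22 and 0.305 in AML arrays, and 0.09 and 0.04 against 0.20 and 0.21 in DC arrays. The 7 replicates may thus hold fewer than 7 independent batches, which the standard errors do not allow for. An immediate-early response during cell isolation was considered because a gene of this kind had been seen to differ in the same arrays. That gene was taken out of the list. Of the 10 genes left, 8 were higher in replicates 1 to 3 (median 0.209, camera p with an estimated correlation = 0.0320). Genes of such a list can move together with the one taken out, so this is no independent test of the explanation, which stays open. This list does not say which step of the work differed, and no biological explanation was tested, since the design gives no group that follows the numbers. The AML effect differed between the sets in 1 gene and the DC effect in 0. With 3 and 4 arrays per medium these counts do not show that the effects were equal. Of the 541 calls for AML against fresh medium, 208 recurred in the same direction in replicates 1 to 3 alone and 26 in replicates 4 to 7 alone. These fits also have fewer arrays to call genes with.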

How the results depend on the processing

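Added after the data were seen were the fits without AML replicates 4 and 5, with a block for both sets of replicates, and within each set. The TGF-beta list kept its call and direction under all 36 alternatives in both AML comparisons (medians 0.72 to 0.82 against fresh medium and 0.32, in replicates 1 to 3 alone, to 0.78 against DC-conditioned medium), and no named gene that was called changed sign. Values that moved are given by setting, though not for every gene and list. Over the alternatives the median of the unfolded protein response, DC against fresh medium, ran from 0.04 to 0.175. Except where fewer samples explain a move, its cause was not tested. As RMA values carry no background measure, dim genes limit the precision in a way that was not measured.

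With a replicate block, 1012 genes were called for AML against fresh medium, 784 for AML against DC and 1 for DC against fresh medium, and the overlap of calls between AML- and DC-conditioned medium was 1; it ended no call among the named genes and lists, and gave calls to *Hk2*, *Il2ra* and *Myc* against fresh medium and to *Cd4* and *Il2ra* against DC. Other settings also gave calls to *Hk2*, *Il2ra*, *Myc*, *Cd4* and, with trend and robust estimation, *Ldha* against DC (adjusted p = 0.0378), and leaving out AML replicate 1 or 7 gave one to *Ifng* against DC. The numbers were not taken to pair the arrays: residuals of arrays with the same number correlated on average at 0.0956 (fresh and AML; 3 of 7 over 0.1), 0.223 (6 of 7) and 0.162 (4 of 7), and 3, 2 and 4 of 7 arrays correlated best with their own number. As a random effect, the number gave 1 DC gene and an overlap of 1. The block for both sets gave 1026, 797 and 1 genes and an overlap of 1.

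Quantile normalization again left 1 DC list. Median centring gave 289 higher and 197 lower calls for AML against fresh medium, 59.5% higher against 46.8%. Leaving out dim genes moved the planned gap between the T cell and stromal lists from 68.0 to 71.2 percentile points, which compares levels of different probes and carries no conclusion. Array weights gave 2 DC genes, 11 DC lists and an overlap of 2. Only the 2 groups compared gave 246 and 26 (2-fold) genes for AML against fresh medium and 249 and 27 for AML against DC. Welch tests gave 21 and 3, and 7 and 1. These settings have fewer arrays or no shared spread, and the spread itself differed between the groups, which the main fit does not allow for. An estimated correlation left 1, 0 and 1 lists (AML against fresh, DC against fresh, AML against DC), and fry 8 for AML against fresh and 0 for DC. With divided controls the correlation of effects was 0.0279 and the overlap 0.0143.

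Without AML replicates 4 and 5, 111 genes (7 at 2-fold) and 92 (6) were called in the AML comparisons, 108 and 87 of them among the original calls, with 1 DC gene and an overlap of 1; 21 of 36 and 23 of 44 called named genes lost the call, and mitosis turned to 0.032 against fresh medium. Replicates 1 to 3 alone gave 63 genes at 2-fold for AML against fresh medium, 2 DC lists, 15 lists for AML against DC and a correlation of 0.512; mitosis turned to 0.081 against fresh medium and 0.023 against DC, S phase to 0.079 against DC, and for DC against fresh medium pentose phosphate turned to -0.057, respiration to -0.055 and MYC targets to -0.10. Replicates 4 to 7 alone gave 32 (7) and 43 (13) genes and 11 DC lists.

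Leaving out each array in turn gave 218 to 776 genes for AML against fresh medium, lowest without AML replicate 5 (AML replicate 4: 249; fresh replicates 2 and 4: 299 and 341), and 24 to 68 at 2-fold (AML replicates 4, 5, 6 and 7: 24, 25, 67 and 68). AML against DC gave 220 to 784 (AML replicates 4, 5 and 6: 220, 242 and 784; DC replicates 4 and 7: 308 and 289) and 24 to 69 at 2-fold (AML replicates 4 and 5: 24 and 29). DC against fresh medium gave 0 to 2 genes and 0 to 10 lists, and the overlap was 0 to 1.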

Other observations

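Replicates 1 to 3 and 4 to 7, groups that no label gives, differed in expression. Of 2839 genes that differed over all 21 arrays with limma after Benjamini-Hochberg adjustment, 1195 were higher in replicates 1 to 3. The split had been noticed in the same arrays, so these calls and the list tests describe it and are no independent test of it. They included the natural killer receptor genes *Klra6*, higher by 1.42, and *Klrd1*, higher by 1.05, and *Gzma*, higher by 1.09. Lower in replicates 1 to 3 were *Spats2* at -1.28, *Cd24a*, a surface glycoprotein of immature lymphocytes, at -1.03 and *Srm*, the spermidine synthase gene, at -0.97. The lists of T cell identity, cytotoxic molecules, naive and memory genes, CD4 T cells and NK cells were higher and the pentose phosphate and nucleotide list lower with an estimated correlation.

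Several programmes that T cell studies often examine did not pass as lists after AML-conditioned medium against fresh medium. Cytotoxic effector molecules had a median of -0.12 over 16 members (adjusted p = 0.113), although *Gzma* fell, and inhibitory receptors a median of 0.04 over 20 members (adjusted p = 0.150). Effector transcription factors had a median of -0.21 over 13 members (adjusted p = 0.0539) and S phase genes a median of -0.10 over 27 members (adjusted p = 0.0824). Against DC-conditioned medium the cytotoxic, effector transcription factor and S phase lists passed with the preset correlation and not with an estimated one. Chemokine receptors and homing genes had a median of -0.05 and a mean of 0.20 over 18 members, opposite in sign, with an adjusted p of 0.817. The lists of B cells, macrophages and monocytes, neutrophils and dendritic cells, cells whose RNA the beads could have left in the samples, had medians between -0.06 and 0.05 and did not pass. The NK cell list, which holds *Gzma*, did not pass either (adjusted p = 0.686), with a median of 0.13 and a mean of -0.14, and its array means lay below all 14 other arrays in 4 of 7 AML arrays. The plasma cell list (adjusted p = 0.789) had a mean of -0.16 and lay below them in 3 of 7. No value decides how much of their RNA was present in the samples.

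Chance was tested by splitting the 14 arrays of each comparison in other ways, 100 splits each with the real one included. For AML-conditioned against fresh medium 1 split, the real one, reached the 541 genes called, and the highest other gave 0. For those changed at least 2-fold 1 split reached 41 and the highest other gave 0. Both counts argue against a chance assignment of single arrays, as far as 100 splits can resolve. The gene counts were not repeated on splits that balance replicates 1 to 3 and 4 to 7. Arrays that move together in sets are therefore not covered. For AML-conditioned against DC-conditioned medium, within the same limits, the 466 genes called were reached in 1 split with 0 as the highest other. Chance was also opposed for the 48 changed at least 2-fold, reached in 1 split with 0 as the highest other. It cannot be excluded for the number of lists called with the preset correlation: 10 splits gave at least the 16 lists of AML against fresh medium (highest other 21), 7 splits at least the 23 of AML against DC (highest other 27) and 48 splits at least the 6 of DC against fresh medium (highest other 23). In 100 further splits, chosen after these results, each side held as many of replicates 1 to 3 as the real groups. There 17 gave at least the 16 lists of AML against fresh medium (highest other 18) and 15 at least the 6 of DC against fresh medium (highest other 11), so chance is still not excluded. For AML against DC 4 gave at least the 23 lists (highest other 24). As these splits were chosen after the planned ones had left chance open, they do not exclude it for that count either. For the 0 genes of DC against fresh medium the test is empty, since all 100 splits reach a count of 0 (highest other 7, and 0 at 2-fold).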
